A study of Homo sapiens with 3 samples.

How the data were processed

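The study enriched RNA from K562 cells, a human leukaemia line of erythroid and myeloid character, for the ends of introns and sequenced it in order to find branchpoint nucleotides, the intron bases to which the cut 5′ end is joined during splicing. The 3 libraries are biological replicates of this line, per the labels' protocols. They form 1 group, so the labels give no comparison between groups. Per the labels' protocols, total RNA was depleted of ribosomal RNA starting from 5 µg, and ERCC spike-in RNA was added to a final 1% in replicates 1 and 2 and 1.08% in replicate 3. Read alignments, branchpoint calls and read depths of the 3 libraries were not analysed here. Whether a sequencing depth stands behind the deposited score is not given in the sources used here. The values come from the deposited list of genomic intervals of the capture probe design, which is common to all 3 libraries.

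Per the labels' protocols, the authors targeted the 100 nt at each end of every intron in GENCODE release 12. They removed parts that overlapped annotated exons or were highly transcribed in public K562 RNA-seq alignments, and the array maker left out repeats. Probes for the ERCC controls and for 30 spliced control genes were added to the array and were not analysed here. The submitters' processing notes name the genome build hg19 and the tools Bowtie2, TopHat2 and bedtools. Which of them made the interval list is not given in the sources used here. Each interval has a chromosome, a start, an end, a running number within its chromosome, a plus strand sign and a score. The deposited score is a whole number of 0 or more whose meaning and normalisation are not given in the sources used here. It was therefore treated as a score and not as a read count, and no count model was fitted. A fixed list has no replicate error: counts and shares over it are a census. Where a spread is given, it is the spread between chromosomes, or a 95% bootstrap interval from 1000 resamples of the 1 Mb windows of a chromosome.

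Coordinates are hg19 and 1-based. Gene names and gene parts could not be attached to single intervals, because the gene annotation used here, GENCODE release 29, lies on another build (GRCh38) and coordinates were neither mixed nor converted. The planned counts of introns with both termini targeted, the comparison of 5′ with 3′ termini and the comparison of gene lists (ribosomal proteins, snoRNA hosts, erythroid and K562 genes, neuronal genes, spliceosome genes, long noncoding RNAs and intronless genes) all needed that join and were not run. The rule for named genes therefore named only regions: the 5 widest intervals, with ties broken by position, and the 3 chromosomes at each end of the density range. The 1 Mb windows, the runs of score 0 and chromosomes 1 and 2 were singled out after their values were seen. Only lengths and totals per chromosome were taken from GENCODE release 29. From it, the 100 nt termini of all distinct introns were laid out, exons were subtracted and the rest merged. This gave a rebuilt set that follows the stated recipe without its repeat and transcription steps.

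Intervals were merged where they overlapped. Gaps were measured between neighbouring intervals. Density is targeted kb per Mb of the span from the first to the last interval of a chromosome. The remainder after division by 3 was taken over gaps of 30 to 400 nt. Gap and internal exon lengths were compared as histograms after subtraction of a 9 nt running mean, at shifts of -3 to 3 nt. Relations across the 23 chromosomes other than Y were tested with two-sided permutation tests of 100000 resamples (shuffled pairs for correlations, flipped signs for differences), and 3 such tests were adjusted together by the Benjamini-Hochberg method. Chromosomes are large blocks, not replicates of an experiment. For the difference, the p-value measures only whether its direction recurs across chromosomes. For a correlation, it measures only whether the 23 pairs of chromosome values go together more than shuffled pairs do. Spearman's rho between neighbouring scores is across intervals, which are not independent. As checks of the code, interval sets were built from 1 chromosome of the annotation with the left edge moved by 0, 1 or 2 nt. Each was assigned its true shift against exons of the same annotation, so a design and exons from different releases were not covered. All of 50 and of 500 inner intervals removed from a renumbered chromosome were found, which checks only the counting. In simulated data, the sign-flip test gave p at or under 0.05 in 6.2% of 500 null draws. Choices of merging, width window, gap limit and density measure, with their alternatives, were fixed before the data were examined. Everything done with the score, the remainders, the rebuilt set and the interval numbers was chosen afterwards. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.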

Results

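The capture design behind 3 K562 branchpoint libraries was examined as a list of 377858 genomic intervals on the 22 autosomes, X and Y. Branchpoints lie near the 3′ ends of introns, and the reads that reveal them join the 5′ end of an intron to a base near its 3′ end, so the design addressed both ends. The libraries are replicates 1, 2 and 3 of 1 group, and the interval list belongs to all of them. It describes which regions were listed as targets, not how much RNA was captured.

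The intervals covered 37.6 Mb (37610114 bases), and none overlapped or touched another. The labels state a design of 36.8 Mb, so the list covered 2.20% (0.81 Mb) more than the stated size. Whether the list is the final design or the targets before the array maker left out repeats is not given in the sources used here. The labels also state that both termini were targeted for 206747 introns (76.4%) and at least 1 terminus for 244125 introns (90.2%). Those intron counts were not recomputed, because no annotation of the hg19 build was used here. The same recipe laid over the 361387 distinct introns of GENCODE release 29, without removing repeats or transcribed regions, gave 443467 intervals and 44.2 Mb. The deposited list held 85.2% as many intervals as this rebuilt set. That share mixes the difference in GENCODE release with the removal steps.

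Most target intervals had the 100 nt width stated for a targeted intron end. Exactly 100 nt was the width of 331436 intervals (87.7%), against 90.9% in the rebuilt set. Intervals of 1 to 69 nt made up 2.23% (8413), those of 70 to 95 nt 3.08% (11636), and those of 96 to 99 nt 2.57% (9701). At 101 nt lay 3951 intervals (1.05%), against 0.07% (308 intervals) in the rebuilt set, and 12721 (3.37%) were wider, up to 201 nt. The widest were chromosome 11 from 65655604 to 65655804 (201 nt, score 73), chromosome X from 47863102 to 47863302 (201 nt, score 54). They were followed by 93 intervals of 200 nt, of which the first 3 by position, all on chromosome 1, ran from 1981106 to 1981305 (score 0), from 3417329 to 3417528 (score 0) and from 22160108 to 22160307 (score 32).

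**Figure D1:**
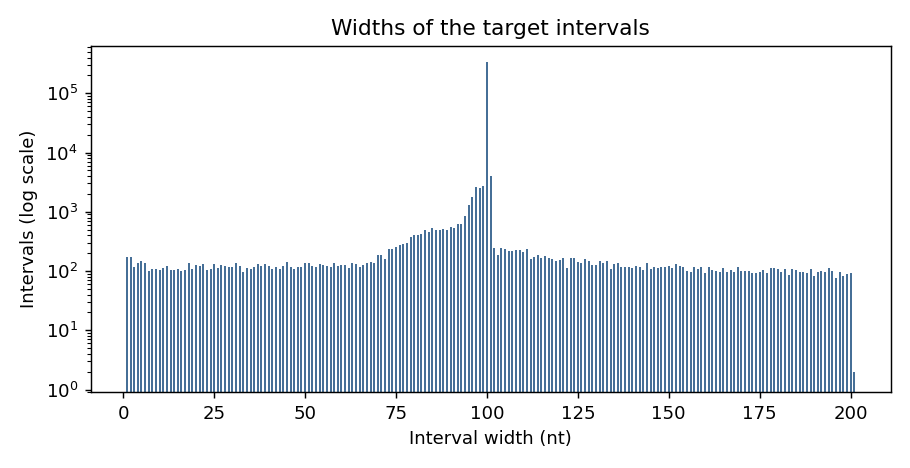
Number of target intervals (log scale) at each interval width in nt, over all 24 chromosomes. The 331436 intervals of 100 nt stand above all others, with a shoulder just below 100 nt and a single peak of 3951 at 101 nt.

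Chromosomes 1 and 2 differed from the other 22 in interval width. Intervals of 96 to 99 nt were 10.6% of those on chromosome 1 and 9.27% of those on chromosome 2. On the other 22 chromosomes the share ran from 0.19% on Y to 1.23% on chromosome 12. Full-width intervals made up 79.5% on chromosomes 1 and 2 together and 89.5% elsewhere. The 2 chromosomes held 68300 of the intervals, and relations across chromosomes are given with and without them.

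**Figure D2:**
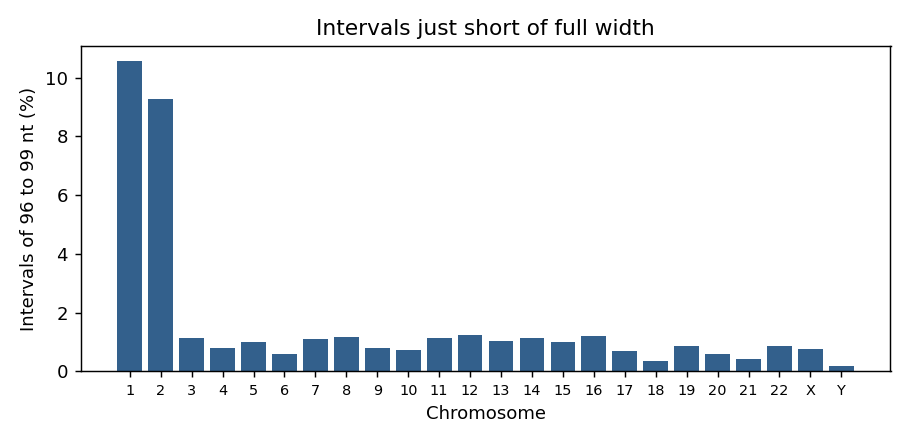
Share of target intervals that were 96 to 99 nt wide (%), one bar per chromosome. Chromosomes 1 (10.6%) and 2 (9.27%) stand apart from the other 22, of which the highest is chromosome 12 at 1.23%.

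Neighbouring intervals were often an exon's length apart, as exons were left out of the design. Of 377834 gaps between neighbours, 58.6% (221321) were at most 1000 nt, with a median of 148 nt and quartiles of 98 and 279 nt. The corresponding median in the rebuilt set was 151 nt. Gap lengths had a period of 3 nt: among 175023 gaps of 30 to 400 nt, 38.0% left 1 when divided by 3, 31.1% left 0 and 30.9% left 2. A remainder of 1 was the commonest on all 24 chromosomes, with shares from 34.8% on chromosome 22 to 41.8% on Y. The 10 commonest gap lengths, led by 97 nt (1471 gaps), 109 nt (1424) and 127 nt (1399), all left 1. Internal exons of GENCODE release 29 had another preference: of 230548 such exons of 30 to 400 nt, 38.8% were multiples of 3, 30.8% left 1 and 30.4% left 2.

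**Figure D3:**
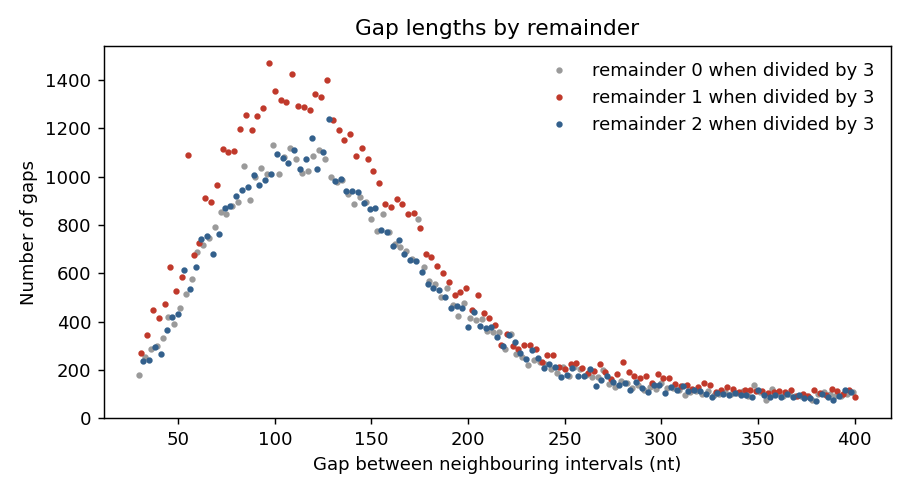
Number of gaps of each length in nt between neighbouring target intervals, from 30 to 400 nt, coloured by the remainder of the length after division by 3. Lengths that leave 1 (38.0% of these gaps) lie above the other two classes over most of the range up to about 200 nt.

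Target density differed between chromosomes. Chromosome 19, known as the most gene-rich, had 31.5 targeted kb per Mb of its span, chromosome 17 had 24.5 and chromosome 22 had 22.2. The sparsest were Y with 2.74, chromosome 18 with 7.57 and chromosome 13 with 7.89, and the median of the 24 was 11.9. The densest exceeded the sparsest 11.5-fold, and 4.17-fold when Y was left out. Without stretches of over 1 Mb that held no interval, which remove most of the long empty part of Y, the range over all 24 narrowed to 4.61-fold. Relative to the rebuilt set, Y held 51.9% as many intervals, chromosome 18 held 72.0% and chromosome 10 held 89.7%, with a median of 86.0% over chromosomes. These shares also mix the difference in GENCODE release with the removal steps.

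Each interval carried a score between 0 and 125. Its meaning is not given in the sources used here. The score was 0 for 178337 intervals (47.2%), its median was 1, its upper quartile 6 and its 99th percentile 82, and 54 intervals had the highest value. The 10.4% of intervals that scored 19 or more (39119) held 65.8% of the summed score. All 1614 intervals on Y scored 0. Of the other chromosomes, 19 had the highest mean score per interval, 12.8 (95% bootstrap interval 11.3 to 14.3). Chromosome 17 followed with 10.0 (8.38 to 11.4), chromosome 16 with 9.82 (8.27 to 11.3) and chromosome 22 with 9.43 (7.24 to 11.8). The lowest means were those of chromosome 2, 3.57 (3.19 to 4.01), and chromosome 13, 4.11 (3.36 to 4.87). Chromosome 2 is also set apart by interval width, as is chromosome 1, which had a mean of 6.09 (5.41 to 6.75). The mean was 4.98 over chromosomes 1 and 2 together and 7.20 over all others. On X the mean was 7.83 (6.09 to 9.79).

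Densely targeted chromosomes had higher scores. Over the 23 chromosomes other than Y, density and mean score had Pearson's r = 0.76 (two-sided permutation p = 0.00015, adjusted 0.00015) and Spearman's rho = 0.50 (permutation p = 0.016, adjusted 0.016 over 2 correlations). Without chromosomes 19 and 17, the farthest from the median density, r fell to 0.46 (permutation p = 0.036) and rho to 0.34 (permutation p = 0.13), so the rank relation rested on those chromosomes. Without chromosomes 1 and 2, r was 0.80 (permutation p = 0.00012) and rho 0.58 (permutation p = 0.0066). When chromosomes 19 and 17 were left out as well, r was 0.53 (permutation p = 0.02) and rho 0.43 (permutation p = 0.068). A relation within chromosomes 1 and 2 could not be computed from a pair of values. Dense chromosomes also had a larger share of intervals of 70 to 95 nt, from 1.15% on chromosome 18 to 5.25% on chromosome 19 (r = 0.73, permutation p = 0.00012, adjusted 0.00015; rho = 0.75, permutation p = 8e-05, adjusted 0.00016). That relation held without chromosomes 19 and 17 (r = 0.63, permutation p = 0.002; rho = 0.71, permutation p = 0.00055) and without chromosomes 1 and 2 (r = 0.82, permutation p = 4e-05; rho = 0.77, permutation p = 0.0001).

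**Figure D4:**
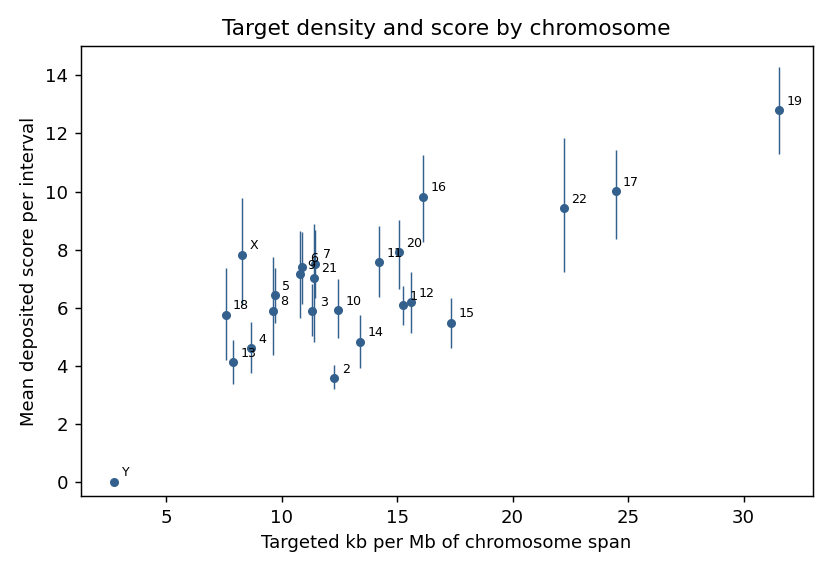
Mean deposited score per interval against targeted kb per Mb of chromosome span, one labelled point per chromosome, with 95% bootstrap intervals over 1 Mb windows. Chromosome 19 lies highest on both axes (31.5 kb per Mb, mean score 12.8), and Y lies at a score of 0.

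Intervals of 70 to 95 nt, a range that can hold whole short introns as well as trimmed intron ends, had a higher mean score than full-width intervals on every chromosome other than Y. Averaged over 23 chromosomes, their mean score was 12.9 ± 4.17 (SD between chromosomes) against 6.43 ± 1.99 for full-width intervals. The difference was 6.45 ± 3.05 (SD, n = 23), positive on 23 of 23 chromosomes, with a sign-flip permutation p of 1e-05, the smallest these resamples can give (adjusted 3e-05). It ranged from 0.96 on chromosome 15 to 13.9 on chromosome 8. The share of intervals that scored above 0 was higher among those of 70 to 95 nt on 22 of 23 chromosomes and lower on chromosome 15 (47.7% against 52.2%). The difference in mean score was 3.63 on chromosome 1 and 5.21 on chromosome 2, and 6.64 ± 3.12 (SD, n = 21) on the others. The highest median of any width class was that of intervals of 96 to 99 nt, which had a median score of 5, a mean of 7.34 and a score of 0 in 21.9%. Their median was 6 on chromosomes 1 and 2 and 2 on the others. Over all chromosomes, intervals wider than 101 nt had a median score of 3 and a mean of 13.9, those of 101 nt a median of 2 and a mean of 8.94, and those under 70 nt a median of 1 and a mean of 7.01.

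Scores were alike in nearby intervals. Spearman's rho between an interval and the one before it was 0.78 for 168394 pairs up to 300 nt apart, with 0.69 and 0.81 as the lowest and highest single chromosome. It was 0.76 for pairs of 301 to 1000 nt, 0.70 for pairs of 1001 to 10000 nt, 0.45 for pairs of 10001 to 100000 nt and 0.19 for 4940 pairs farther apart. Of 2055 windows of 1 Mb with at least 50 intervals, the median of the mean scores was 4.62. The highest mean was 30.7, on X from 64000001 to 65000000 (57 intervals). On chromosome 22 the window from 22000001 to 23000000 reached 29.02 (159 intervals) and that from 19000001 to 20000000 reached 26.6 (312 intervals). On chromosome 8 the window from 145000001 to 146000000 reached 27.3 (460 intervals).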

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

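Both tests of the missing interval numbers were set before their values were computed. It was already known by then that no number was missing on Y, and a few single intervals had been seen. Intervals are numbered along each chromosome, and 4753 of 382611 numbers (1.24%) were missing, all of them on the 23 chromosomes other than Y. The missing numbers are a signal in a field that no comparison above uses. Chromosome 19 missed the largest share of its numbers (3.82%, 734) and chromosome 13 the smallest of those with any (0.35%, 27).

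The tables argue against removal of numbered candidates as repeats without regard to score, since the share of score 0 was 41.3 percentage points lower next to missing numbers than elsewhere (6.39% against 47.6%). Removal of candidates whose score passed an upper limit is a candidate explanation that stays open. It predicted higher scores next to missing numbers, and the median there was 30 against 1 elsewhere, higher on 23 of 23 chromosomes. An upper limit would also end the scores abruptly, and they did end so: 54 intervals scored 124, 54 scored 125 and none scored more. That stop was not part of the prediction. The scores of the removed candidates themselves are not known. The labels' protocols do state that parts highly transcribed in public K562 RNA-seq alignments were removed. Whether the score measures that transcription is not given, so the missing numbers cannot be tied to this step. Any removal that was commoner in high-scoring genes would also leave higher scores next to missing numbers, but need not give such a stop. No biological explanation was tested.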

How the results depend on the processing

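All alternatives that concern chromosomes 1 and 2, the score, the remainders or the rebuilt set were chosen after the data were seen. The covered length stayed within 1.5 times under the 3 alternatives fixed beforehand. Merging gaps of up to 10 nt gave 37618958 bases, and the other two left it unchanged because no interval overlapped another or lay outside the 24 chromosomes. The share of full-width intervals was 93.0% with a window of 90 to 110 nt and 89.5% without chromosomes 1 and 2. The median gap was 132 nt for gaps up to 500 nt and 124 nt for gaps up to 300 nt, since each limit removes long gaps. The range of density over chromosomes was 11.5-fold (11.48) by number of intervals and 4.61-fold without empty stretches over 1 Mb, which shorten the span of Y. The relation of density to mean score and the higher score of 70 to 95 nt intervals kept their direction and stayed past the 0.05 threshold in permutation tests under each alternative run. For mean score, r ran from 0.46 to 0.80 (rho missed the threshold without chromosomes 19 and 17). With the share of intervals scoring above 0 in place of mean score, r was 0.86. Differences in mean score between the width classes ran from 6.29 to 7.19. The share of gaps that left 1 was 38.1% for gaps of 60 to 200 nt and 38.7% between full-width intervals. The rebuilt set had 435420 intervals with the basic transcripts. Alternatives for the counts of introns with both termini targeted, for 5′ against 3′ termini and for gene lists were not run, as no annotation of the same build was used. No paired analysis was possible because the labels give 1 group and the list holds no value per library. Leaving out replicates was not possible for the same reason. No reads were counted here, and whether the deposited score depends on a sequencing depth is not given in the sources used here.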

Other observations

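Some stretches of the genome held only intervals with score 0. Outside Y, 48 runs of at least 100 consecutive intervals scored 0. The longest by number was on chromosome 12 from 80839171 to 82386210 (241 intervals over 1.55 Mb). The longest by distance was on chromosome 9 from 20757989 to 25784412 (221 intervals over 5.03 Mb), followed by chromosome 10 from 52580211 to 57387383 (212 intervals over 4.81 Mb) and chromosome 4 from 90757177 to 95128679 (113 intervals over 4.37 Mb). On X, a run from 31893204 to 35816772 held 115 intervals over 3.92 Mb. On Y, all 1614 intervals scored 0. Of these, 221 had an interval of equal width on X at an offset of 50000 nt, the commonest offset, and 1393 (86.3%) had none at that offset, while the next commonest offset paired 36. Of the 221 X intervals paired at 50000 nt, 138 (62.4%) scored above 0, against 52.6% of the other X intervals. Gaps of 55 nt were commoner than the neighbouring lengths of the same remainder, with 1089 gaps against 584 of 52 nt and 676 of 58 nt. Internal exons of GENCODE release 29 had the same kind of peak at 54 nt, the exon length known from fibrillar collagen genes, with 1581 exons against 929 of 51 nt and 1032 of 57 nt. These lengths and runs were picked after their values were seen, and which genes they come from was not examined.

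The excess of gaps that leave 1 when divided by 3 may come from interval edges that lie 1 nt inside the intron at one end, so that a gap is an exon plus 1 nt. These tests were chosen after the pattern was seen. Over shifts of -3 to 3 nt, gap lengths matched internal exon lengths best at a shift of 1 nt (r = 0.96 across lengths). The next best was -2 nt (r = 0.70), and r was -0.38 at 0 nt. The period of 3 nt already favours both 1 and -2 nt, so only the contrast between these 2 shifts adds to the remainders. Exon lengths themselves do not have the pattern, as 30.8% left 1. A rebuilt set with the left edge moved 1 nt inward gave 37.7% of gaps with a remainder of 1, 7149 intervals of 101 nt and a widest interval of 201 nt, against 31.2%, 308 and 200 nt without the move. With the basic transcripts alone, the move gave 38.4%, 4141 and 201 nt, against 30.9%, 320 and 200 nt without it, so the number of 101 nt intervals depends on the transcript set. The deposited list has 38.0%, 3951 and 201 nt. A move of the right edge by the same amount was not run, and which splice site base is left out depends on the strand of the intron, as every interval is listed on the plus strand.

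Intervals 1 to 4 nt short of full width were common on chromosomes 1 and 2 alone, and the labels name no step that treated these chromosomes apart. The gap and rebuilt-set tests were set before their results were seen, the score test afterwards. The tables argue against a feature of the annotation, as far as release 29 can stand for release 12, since the rebuilt shares of 96 to 99 nt were 0.68% on chromosome 1 and 0.80% on chromosome 2, within 0.29% to 1.10% on the other 22. With the same limit, they argue against ordinary removal of exon parts as the source of the excess. The rebuilt set includes that step, and the deposited shares were 10.6% and 9.27%. Gaps between such an interval and a full-width one left 1 in 32.5% of 3289 cases as listed. Once the missing bases were given back, 37.1% left 1, as they would if bases were missing at the exon side. On the other 22 chromosomes the same share moved from 33.2% to 36.04% over 2471 gaps. The gap test alone therefore cannot single out a cut made only on chromosomes 1 and 2. The share with score 0 was 39.2 percentage points lower among the 96 to 99 nt intervals than among full-width ones on chromosomes 1 and 2 (14.8% against 53.97%), and 9.33 points lower on the others (38.7% against 48.1%), so a cut that depended on what the score measures may account for the excess. This is a hypothesis formed on the same values: the meaning of the score is not given, so it cannot be read as transcription here, and the difference between these drops was not tested.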
